A study of Homo sapiens with 4 samples.

How the data were processed

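RNA bound by Tino (hMEX-3D, a human RNA-binding protein with KH domains and a RING finger) was hybridized to Affymetrix expression arrays in 4 samples. Per the labels' protocols, HEK293 cells, a human embryonic kidney line, were transfected transiently and harvested 2 to 3 days later, and biotin-labelled cRNA was made from 6 µg of RNA by Affymetrix's standard procedure. The first pair of arrays holds RNA immunoprecipitated from cells given His-tagged Tino and its negative control from mock cells (the in vivo arm). The second pair holds RNA made from a placental cDNA library and kept on nitrocellulose by a His-tagged Tino without its RING finger, and the control filter without protein (the in vitro arm). Each of the 4 groups has 1 array, so no test across replicates exists and no p-value is given. The number of arrays limits the precision of every value.

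The deposited table holds, per the file headers, a z-score per probe set and array and a z-ratio per probe set and arm, both computed by the authors and read here as the unit score. It lists 22277 probe sets for the in vivo arm, of which 62 are Affymetrix controls, and 1367 for the in vitro arm, of which 1 is a control. A probe set is a group of short probes that read 1 transcript or several related ones. The signal algorithm, the array scaling and the filters behind the table are not given in the sources used here. All 6 columns of values were matched to a sample or an arm through their header names and the sample titles. The z-ratio equalled the difference of the z-scores divided by the SD of all differences in the arm, 1.17 in vivo and 1.49 in vitro, to within 0.000132.

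On each array the z-scores were spaced as logarithms of whole numbers. The deposited z-scores could therefore be turned back into whole-number signals, up to the unit of 1 step, by fitting z as a straight line in the logarithm of a whole number. Every z-score lay within 0.0001 of such a value on all 4 arrays. Rounding to 4 decimals leaves the number of steps exactly fixed for 99.7% and 99.8% of probe sets on the Tino and mock arrays, and for 95.1% and 99.3% on the filter arrays with and without protein. On simulated arrays of the same size and spread, 99.98%, 100%, 95.8% and 99.3% of signals came back exactly, and the largest relative error was 0.017%. The lowest simulated values were set to consecutive whole numbers starting at the fitted lowest step. The simulation therefore covers rounding and cannot test the choice of the unit. Signals are given below in these steps, and signal ratios assume that 1 step is the same on both arrays of an arm. This is an assumption in both arms. In vivo the hybridization spike-ins gave nearly equal numbers of steps on both arrays, and in vitro no spike-in is listed.

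The in vitro z-scores had a mean of 0 and an SD of 1 over the 1367 listed probe sets alone. No listed probe set had a signal ratio between 2.90-fold lower and 2.62-fold higher than the control, so this part of the table holds changed probe sets alone; the rule that selected them is not given in the sources used here. Its z-ratios measure distance from the middle of that list, not from equal signal, and they are not on the scale of the in vivo z-ratios. A z-ratio of 0 is not equal signal in vivo either, since each array was centred and scaled on its own. The fitted lines imply scaling by a mean natural log of signal of 2.96 and an SD of 1.78 on the Tino array. For the mock array they imply a mean of 1.98 and an SD of 1.42. The listed z-scores had SDs of 0.9985 and 0.9969 on these arrays, so the scaling may have used other probe sets as well. At 10 steps on both arrays the z-ratio would be -0.51, and at 10000 steps it would be -1.34.

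Before the data were examined, a z-ratio of 1.5 either way was set as the threshold, together with stricter ones of 1.96 and 3, rules for naming genes and 24 gene lists. The table gives probe set IDs and no gene names. None of the 22277 IDs is in the gene table used here (GRCh38.p14), so no gene list, gene value or gene-level choice could be used. BCL2, the reported target of Tino, and the MEX3 genes themselves are for the same reason not analysed here. In place of the rule for named genes, which took the 15 highest and 5 lowest genes per arm and the 10 highest over both, the 2 highest and the 2 lowest probe sets of the in vivo z-ratio are given by ID. The transcripts that Affymetrix's control probe sets carry in their IDs are named too. They are the hybridization spike-ins, added to every sample before hybridization, the Bacillus genes, which have no human counterpart, and human GAPDH, beta-actin, STAT1, ribosomal RNA and Alu. The signals of the 27 Bacillus probe sets reached at most 27 steps on either array, and this value was used as the background level in vivo. A fold against a signal at or below it was computed against 27 steps and is written as "at least". Such a fold is a lower bound only if the background did not exceed 27 steps. No fold is given where both signals are at or below it. The recovery of signals, the signal ratios (with no pseudocount added) and the use of the in vitro lists as lists in vivo were chosen after seeing the data. An offset planned for deposited signals was not used, since the table holds none.

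The arms were compared over the 1366 probe sets that both list and that are not controls. Overlaps are set beside the count that independent lists would give. For the whole in vitro lists that count was taken over all 22215 in vivo probe sets that are not controls. Correlations across probe sets are descriptive, because probe sets are not independent replicates; their 95% intervals come from 1000 resamples of probe sets. The median in vivo z-ratio of the probe sets listed as higher or lower in vitro was set beside 10000 random lists of the same size, matched in 100 bins of mean log2 signal in vivo, a number raised from a smaller one when simulated lists with no shift fell outside too often. On simulated lists with no shift, 3 of 100 fell outside the central 95% of random lists, and with a shift of 0.5 all 100 did. The 3 of 100 was counted after that change, so it is no independent check of the bins. Simulated values were not computed from the 2 signals, and simulated lists were drawn by mean signal. A list that differs in brightness on the Tino array alone was therefore not simulated. The alternatives were the stricter thresholds, probe sets without _s_at and _x_at IDs (which can match several transcripts), a filter at the 40th percentile on the bound-RNA array, the top 100, 250 and 500 of each arm, and unmatched random lists. Added after seeing the data were signal ratios past 4-fold, with and without a floor at 27 steps, the whole in vitro lists, and probe sets above the median of in vivo signal. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.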

Results

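To find transcripts bound by the RNA-binding protein Tino, RNA was collected in 2 ways and hybridized to Affymetrix arrays. In the in vivo arm, His-tagged Tino was immunoprecipitated from transfected HEK293 cells with its bound RNA and compared with a mock control. In the in vitro arm, RNA from a placental cDNA library that Tino without its RING finger (TinoΔRING-his) held on a filter was compared with a filter without protein. Each group had 1 array, and the values below carry no replicate error. The median signal over 22277 probe sets was 19 steps on the Tino array and 7 on the mock array. Over the 1367 probe sets listed in vitro it was 666 steps with the protein and 175 without.

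The in vivo comparison asked which transcripts came down with Tino in HEK293 cells. Among the named transcripts, GAPDH, a glycolytic enzyme, was lower in the Tino immunoprecipitate than in the mock control at each of its 3 probe sets. Its 5' signals lay near the background level. STAT1, a transcription factor of interferon signalling, and beta-actin, a cytoskeletal protein, were higher at their 3' probe sets. Ribosomal RNA gave opposite directions along the same molecule. On both arrays GAPDH gave far more signal at its 3' than at its 5' probe set, 580 against 21 steps with Tino and 1673 against 41 in the mock. How intact the RNA was on each array was not assessed. Differences between positions were therefore not read as a feature of what Tino bound. Over all probe sets the median log2 signal ratio was 1, but 55.7% of probe sets had both signals at or below the Bacillus maximum of 27 steps, and this shift was not used as a reference.

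The GAPDH 3' probe set read 580 against 1673 steps, 2.88-fold lower with Tino, and the middle probe set read 155 against 439 steps, 2.83-fold lower. At the 5' probe set GAPDH read 21 against 41 steps, at least 1.52-fold lower. In the authors' deposited table the z-ratios of GAPDH were -1.63 at the 3', -1.46 at the middle and -1.0 at the 5' probe set. On the scale of the authors' deposited table, equal signals would have a z-ratio of -0.51 at 10 steps, -0.79 at 100 steps and -1.06 at 1000 steps. STAT1 read 140 against 3 steps at its 3' probe set, at least 5.19-fold higher with Tino. Its other 3 probe sets stayed at or below 25 steps on both arrays, within the range of the Bacillus controls, which have no human target. Beta-actin was at least 3.52-fold higher with Tino at its 3' probe set, with 95 against 3 steps. Its middle probe set, with 30 against 3 steps, was at least 1.11-fold higher, just above the background level. Its 5' signals lay within the Bacillus range.

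Small-subunit rRNA was 2.69-fold lower with Tino at its 5' probe set, with 352 against 946 steps. At its 3' probe set it read 1133 against 443 steps, 2.56-fold higher, and its middle probe set was 1.54-fold higher. Their z-ratios in the authors' deposited table, -0.51 and -0.75, were below 0 but above the -1.39 to -0.93 of the hybridization spike-ins, whose signals were nearly equal. Large-subunit rRNA was at least 8.30-fold higher at its 5' probe set (224 against 5 steps) and 2.52-fold lower in the middle (85 against 214 steps). Its 3' probe set read 29 against 6 steps, at least 1.07-fold higher. Alu repeats, short interspersed elements of the human genome, gave 18260 and 17380 steps, or 1.05-fold more signal with Tino, and a z-ratio of -1.38 in the authors' deposited table, where equal signals of 10000 steps would have -1.34.

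**Figure D1:**
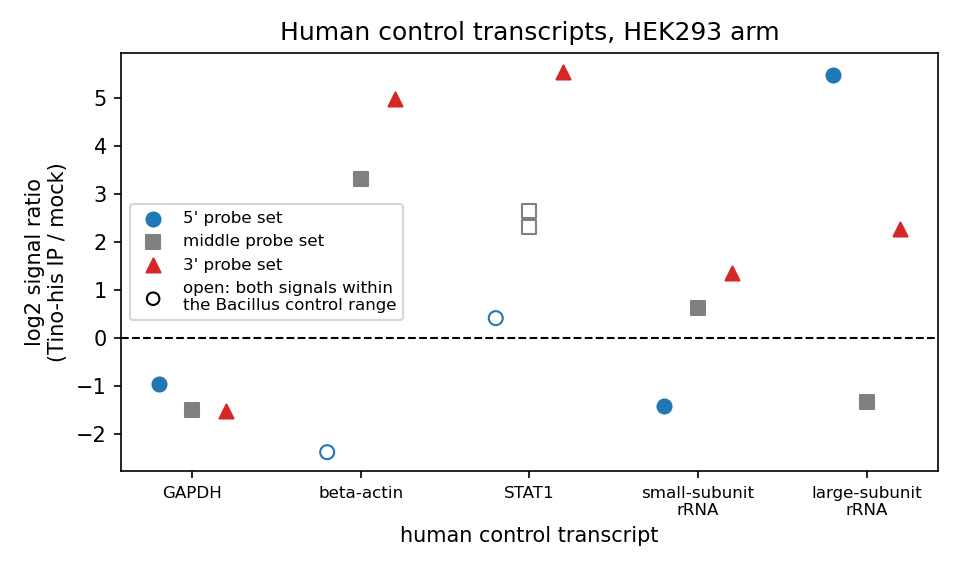
Log2 ratio of signal in the Tino-his immunoprecipitate over the mock control (y axis) for the 5', middle and 3' probe sets of 5 human control transcripts (x axis), 1 array each; open symbols have both signals within the Bacillus control range and carry no fold. GAPDH lies below the dashed line of equal signal at all 3 positions, and beta-actin and STAT1 lie highest at their 3' probe sets.

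The hybridization spike-ins, bacterial bioB, bioC and bioD transcripts and the phage cre transcript, gave nearly equal signals on the Tino and mock arrays. Their log2 signal ratio averaged -0.0066 ± 0.125 (SD over 18 probe sets), with a range from -0.27 to 0.20. The Bacillus controls had a median of 4 steps on each array, and their log2 signal ratio averaged 0.17 ± 1.81 (SD over 27 probe sets). The differences of GAPDH and small-subunit rRNA exceeded the range of the spike-ins. That range covers hybridization and scanning but not the steps before them, among them the immunoprecipitation and the making of labelled cRNA.

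**Figure D2:**
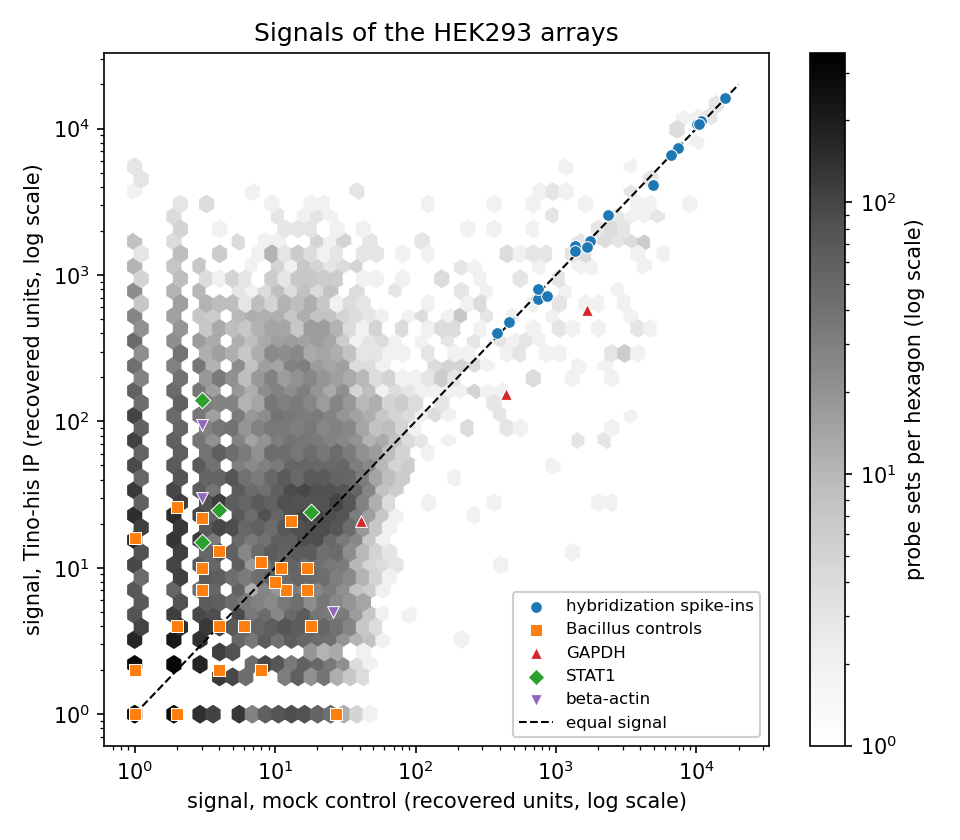
Signal of each probe set on the Tino-his immunoprecipitate array (y axis) against the mock array (x axis), both in recovered steps on log axes; grey hexagons count probe sets, coloured points are control probe sets and the dashed line is equal signal. The hybridization spike-ins lie along the line, the Bacillus controls lie at or below 27 steps on both arrays, and GAPDH lies below the line.

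Across the array, 1762 of 22215 probe sets that are not controls (7.93%) had a z-ratio of 1.5 or more and 1234 (5.55%) had one of -1.5 or less. The probe sets past the upper threshold had a median of 204.5 steps with Tino and 2 in the mock control, and 856 of them (48.6%) were at 1 step in the mock control, the lowest value recorded. Those past the lower threshold had a median of 2 steps with Tino and 25 in the mock control. The highest z-ratios in the authors' deposited table were 3.87 for 210097_s_at and 3.86 for 208374_s_at. With 5167 and 5017 steps against 1 step in the mock control, these were at least 191-fold and 186-fold higher. The lowest z-ratios in the authors' deposited table were -4.82 for 205928_at, with 2 against 3575 steps, and -4.69 for 219136_s_at, with 1 against 1673 steps. These were at least 132-fold and 62.0-fold lower with Tino. The deposited table does not pair these IDs with genes.

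The balance of higher and lower probe sets depended on the scale. Of the calls past the z-ratio threshold, 58.8% were higher with Tino. By a signal ratio past 4-fold with no floor, 8546 probe sets were higher and 2186 lower, so that 79.6% of calls were higher. Of the 27 Bacillus probe sets, which have no human target, 6 also differed by at least 4-fold either way, and 1 passed the z-ratio threshold. With signals floored at the Bacillus maximum of 27 steps, 3059 were higher and 181 lower, or 94.4% higher. Signals above 27 steps were read from 40.1% of probe sets on the Tino array and from 12.2% on the mock array.

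The in vitro comparison asked which transcripts TinoΔRING-his bound outside the cell. STAT1 was the only control transcript listed, at its 3' probe set, and it was 10.2-fold higher with the protein, with 519 against 51 steps. STAT1 was thus higher at this probe set in both arms, with z-ratios of 1.48 in vivo and 0.46 in vitro in the authors' deposited table, neither of them past 1.5. The list held 951 probe sets with more signal on the TinoΔRING-his filter and 416 with less. The higher set had a median of 1133 steps with the protein against 74 without, and a median ratio of 13.2-fold. The lower set had a median of 52 steps against 674.5, and a median ratio of 11.2-fold. The probe set with the highest z-ratio read 1667 against 4 steps, and the one with the lowest read 9 against 2082 steps. A z-ratio of 1.5 or more was reached by 27 probe sets that are not controls and one of -1.5 or less by 136, while 935 and 410 differed by at least 4-fold in signal, so that the share of higher calls was 16.6% on the first scale and 69.5% on the second. No spike-in or Bacillus control was listed, so neither a common scale nor a background level could be checked in this arm, and its folds are plain ratios of recorded steps.

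**Figure D3:**
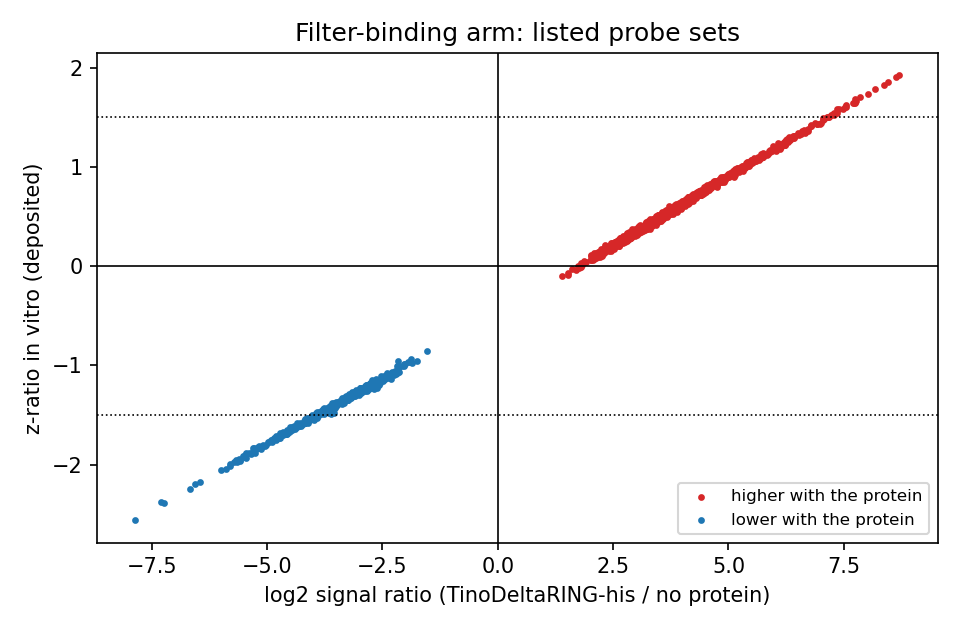
Deposited z-ratio of the filter-binding arm (y axis) against the log2 ratio of signal with TinoΔRING-his over no protein (x axis), 1 point per listed probe set, red for higher and blue for lower signal with the protein, with dotted lines at z-ratios of 1.5 and -1.5. No listed probe set lies between 2.90-fold lower and 2.62-fold higher, and the higher set starts at a z-ratio of -0.098.

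The third comparison asked whether the 2 ways of collecting RNA pointed to the same transcripts. Probe sets higher in vitro were also higher in vivo as a group, while those lower in vitro lay near the background in vivo. The median in vivo z-ratio was 0.93 for the 950 probe sets higher in vitro, -0.29 for the 416 lower in vitro and -0.12 for the 20849 not listed. The set higher in vitro had median signals of 86.5 steps with Tino and 5 in the mock control. The set lower in vitro had medians of 9 and 5 steps and the probe sets not listed had 18 and 7, all within the Bacillus range, so that no in vivo direction was read for the set lower in vitro. Of the 950, 734 (77.3%) had an in vivo z-ratio above 0, against 165 of the 416 (39.7%). Random lists of 950 probe sets were matched on mean signal over the 2 in vivo arrays. Of 10000 such lists, 0 had a median as high as that of the set higher in vitro, and the highest was 0.19. For the set lower in vitro, 18 of 10000 matched lists had a median as low. The matching uses the same 2 signals as the z-ratio, so for both sets it cannot remove brightness on the Tino array alone. These percentiles describe the 4 arrays and are no test across replicates.

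**Figure D4:**
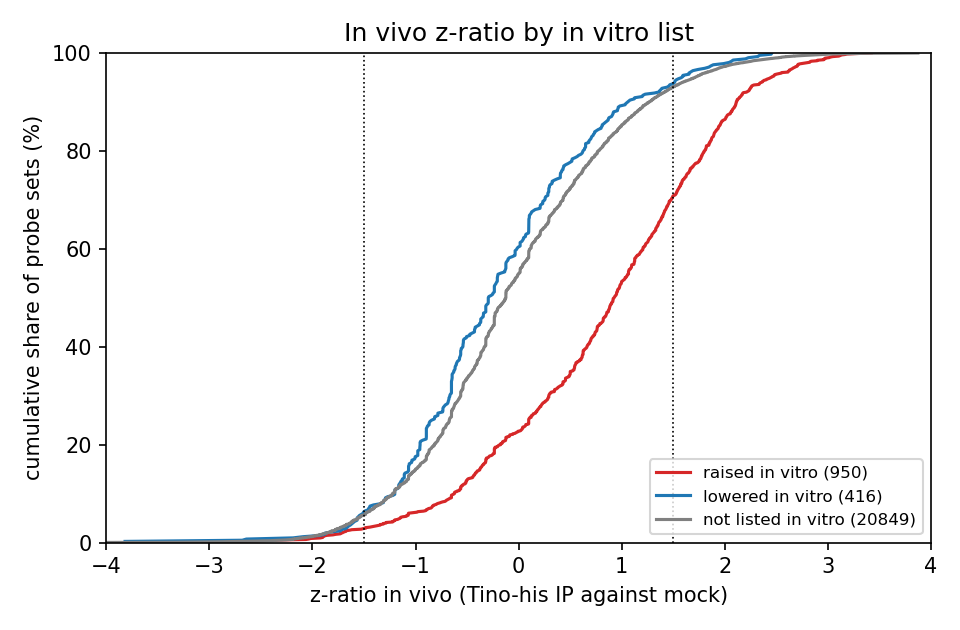
Cumulative share of probe sets (y axis, percent) by in vivo z-ratio (x axis) for probe sets higher in vitro (red, 950), lower in vitro (blue, 416) and not listed in vitro (grey, 20849), with dotted lines at 1.5 and -1.5. The red curve lies to the right, with a median of 0.93 against -0.29 and -0.12.

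By counts, 278 of the 950 probe sets higher in vitro (29.3%) had an in vivo z-ratio of 1.5 or more. Independent lists drawn from all 22215 probe sets that are not controls would share 75.4. A z-ratio of 1.5 asks for at least 37 steps on the Tino array, and 40.1% of these probe sets exceeded 27 steps there. The base thus holds many probe sets too dim to be called, and no count was made among bright ones alone. Of the 416 lower in vitro, 27 reached 1.5 in vivo (6.49%), where independent lists would share 33.0 on the same base. Together, 305 of the 1366 listed in vitro reached it. At an in vivo z-ratio of -1.5 or less, the set higher in vitro had 27 members (52.8 for independent lists) and the set lower in vitro had 26 (23.1). With the threshold of 1.5 in both arms, 6 of the 1366 probe sets listed in both passed it upward, where independent lists would share 6.03, and 12 passed it downward, where they would share 5.28. Of the 6, the highest by the lower of its z-ratios read 57 against 1 step in vivo and 3234 against 15 in vitro. Of the 12, the lowest read 1 against 22 steps in vivo, within the Bacillus range, and 15 against 1538 in vitro. Across the 1366 probe sets, which are not independent replicates, the z-ratios of the arms had a Pearson coefficient of 0.368 (95% interval 0.321 to 0.414) and a Spearman coefficient of 0.311 (0.263 to 0.359). Within the 950 probe sets higher in vitro these coefficients were -0.039 and -0.048, and within the 416 lower in vitro they were 0.030 and 0.018, so the relation lay between the lists and not within them.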

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

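The 4-fold signal ratio, the floor, the whole in vitro lists and the median-signal filter were chosen after seeing the data, and the other alternatives before. Of 40 alternative values, 6 stayed close to the main value and 34 moved. Stricter thresholds, fewer probe sets and top lists change a count by themselves, so this tally does not measure how stable the results are. Close means a count within 1.5 times the main one. For a median it means a difference of at most 1 SD of the random lists' medians. For a correlation it means a difference of at most the mean distance from the main value to the 2 limits of its 95% interval. Where the setting does not itself lower the count, the cause was not tested. At the stricter of the z-ratio thresholds, 769 probe sets were higher and 318 lower in vivo, 0 and 14 in vitro, and 0 and 1 in both arms. At 3 there were 63 and 29 in vivo, and 0 and 0 in vitro. Without _s_at and _x_at probe sets, which leaves fewer probe sets to count, there were 822 and 672 in vivo, 14 and 71 in vitro, and 3 and 4 in both. The median in vivo z-ratio of the list lower in vitro then became -0.21, while the list higher in vitro (0.89) and both correlations stayed close. Above the 40th percentile on the bound-RNA array, 221 probe sets were lower in vivo and 0 in vitro, since this filter itself removes dim bound signals; the 1762 higher in vivo could not change, since each had a bound signal of at least 37 steps. Among the top 100, 250 and 500 of each arm, 16, 41 and 85 of the highest in vivo and 7, 11 and 23 of the lowest were listed in vitro at all, where independent lists would hold 6.15, 15.4 and 30.7. Of the listed ones, 1, 10 and 34 were shared at the upper end, where independent ranks among them would share 1.17, 7.50 and 31.1. At the lower end 1, 3 and 9 were shared, against 0.51, 2.01 and 8.42, and the lowest 500 in vitro also hold probe sets with more signal with the protein, since 416 had less. A signal ratio past 4-fold gave 8546 and 2186 in vivo and 935 and 410 in vitro, and the floor at 27 steps gave 3059 and 181 in vivo. The in vitro balance thus turned from 27 higher and 136 lower to mostly higher calls under the 4-fold ratio. The whole in vitro lists shared 278 higher and 26 lower probe sets with the in vivo calls. Above the median of in vivo signal the list medians were 1.07 and -0.14. Unmatched random lists gave a median of 950 probe sets of at most 0.083, and 1 of 10000 was as low as the list lower in vitro. The gene-level alternatives (mean or farthest probe set per gene, BCL2 and MEX3D by probe set) were not run, as no ID could be matched to a gene. Nor was the z-ratio recomputed from signals, since these come from the z-scores. No paired analysis was possible because each group has 1 array, and no replicate can be left out. In vivo, 55.7% of probe sets had both signals at or below the Bacillus level of 27 steps, and for these no direction can be read.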

Other observations

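The test of the spike-ins below was chosen only after its result was seen, and the other tests before theirs. Probe sets with _s_at IDs, which match several transcripts of a gene or family, reached an in vivo z-ratio of 1.5 in 10.0% (801 of 7974), _at probe sets in 6.98% (822 of 11774) and _x_at probe sets in 5.72% (139 of 2428). At -1.5 or less the shares were 5.22%, 5.70% and 6.01%, and the classes were not matched on signal. Among the 1366 listed in both, 10 passed 1.5 in vivo and -1.5 in vitro, where independent lists would share 30.4, and 0 did the reverse, where they would share 1.05. The probe set with the highest in vitro z-ratio read 360 against 388 steps in vivo, and the next read 278 against 13.

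The hybridization spike-ins had in vivo z-ratios near -1 although their mean log2 signal ratio was -0.0066. The values are consistent with the z-score scaling itself, if a step is the same on both arrays, which no value apart from these spike-ins shows. The Tino array had both a higher mean and a wider spread of log signal than the mock array, and their shares in the shift were not separated. By the same arithmetic, equal signals would have a z-ratio of -0.24 at 1 step and of -1.34 at 10000 steps. No biological explanation was tested for this pattern.

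Probe sets higher in vitro had a higher in vivo z-ratio than those lower in vitro, by 1.22 between the medians. Matching on mean brightness over the 2 in vivo arrays left most of this difference. Within 10 bins of mean signal its median was 1.08, with a range from 0.19, in the dimmest bin, to 1.60. It was 0.94 and 1.22 in the 2 bins with mean signals above the Bacillus maximum, which hold 27 and 15 probe sets lower in vitro. The dimmer bins include signals from which no direction can be read. The bins use the same 2 signals as the z-ratio, so they cannot remove brightness on the Tino array alone. There the higher and lower sets had medians of 86.5 and 9 steps, against 5 and 5 in the mock control, and that explanation stays open. Probe sets that match several transcripts are argued against as the whole cause, since the difference was 1.10 without them (539 and 210 probe sets). Binding by Tino in both assays, the abundance of each transcript in the starting RNA, which no array used here measured, and the unstated filter behind the in vitro list were not tested and stay open.

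Many in vivo calls rest on signals near the lowest step. For z-ratios of -1.5 or less, 57.6% (711 of 1234) had a mock signal within the Bacillus range, and 523 lay above it. The share met the bound set beforehand for signal of the kind that probe sets without a human target give. Over all probe sets that are not controls, however, only 12.2% had a mock signal above 27 steps. The bound could thus be met by most sets of probe sets, and the share does not decide on that explanation. For z-ratios of 1.5 or more, the share with a Tino signal within the Bacillus range was 0%. This was under the bound set for excluding such signal, but that bound was recognised as void after the value was seen. The threshold itself asks for at least 37 steps in the Tino immunoprecipitate when the mock control is at 1 step, above the Bacillus maximum of 27. Whether 27 Bacillus probe sets bound the background of 22215 others stays open.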
